A study of Mus musculus with 6 samples.

How the data were processed

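Per the labels' protocols, bladders were frozen in liquid nitrogen, embedded and sectioned, sections were stained with haematoxylin and eosin, and urothelial cells were dissected by laser capture. Total RNA was extracted with a column kit for small samples, and 100 ng per sample was amplified and labelled for Affymetrix 3' expression arrays, which read each transcript near its 3' end with sets of short probes. Per the submitters' processing notes, Partek and RMA were used, with no version given. RMA corrects background, normalizes all arrays to a common distribution and summarises the probes of a set on a log scale, so a difference in total RNA between samples is removed before the values are seen. The deposited table held 45101 probe sets in log2 units for 6 arrays, with array medians between 6.07 and 6.14, and it was used as deposited. A further table deposited by the authors gave signed fold changes between groups. These equalled 2 raised to the difference of the group means of the deposited log2 values for 45101, 45100 and 45101 of 45101 probe sets in the 3 comparisons, within a tolerance of 0.006, and were not used further. The genome build was not given in the sources used here.

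Probe sets were named through a table of the array's annotation. Of the 45101 probe sets 34958 had 1 gene symbol, 932 had several and 9211 had none in that table. Of the 64 control probe sets 13 had 1 symbol and 51 none, and the 34945 probe sets with 1 symbol that were not controls were tested by name. The Entrez identifiers of 34754 were found in a RefSeq gene table of assembly GRCm38.p6, which was used for current symbols, for the chromosome of a gene and for the order of neighbouring genes, and no coordinate of it is printed. A gene was represented by its probe set with the highest mean over all arrays, which gave 18193 genes, of which 9010 had more than 1 probe set. For the named genes no other probe set of the same gene was called in the opposite direction. Some had other probe sets with little change and no call. Examples are Rptn between the lesions (-0.19 to 0.08) and, in carcinoma in situ against normal urothelium, Cldn1 (-0.08 to 0.29), Notch4 (-0.09 to 0.18), Xaf1 (0.15) and Bub1 (-0.12). The genes altered in the transgenic mice were not analysed here, so the genotype could not be checked from these values.

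Groups were taken from the titles. All 6 arrays entered 1 linear model with 3 group means in limma 3.58.1 under R 4.3.3, with moderated variances (eBayes), so that the 3 groups of 2 arrays shared an estimate of the spread with 3 residual and 2.69 prior degrees of freedom. No filter on dim probe sets was used. P-values are two-sided, were adjusted by the Benjamini-Hochberg method over 18193 genes, and were called at an adjusted p under 0.05. Changes are differences of mean log2 signal with the standard error of the model, and a fold is 2 raised to that difference. RMA compresses small signals, so folds of dim genes are understated.

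Before the data were examined, 33 gene lists with 598 members were fixed, for the urothelium and its lesions, for pathways and for markers of other cell types that a captured region could hold, and 549 memberships were measured. For each list the members past the threshold were counted over all genes and adjusted over the list alone. Lists with at least 4 measured members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 33 lists of a comparison, and again with the correlation estimated from the arrays. Fry, another set test of limma, asked whether the genes of a list moved, on balance, 1 way. The named genes followed a rule fixed at the same time: per comparison the 6 largest rises and 6 largest falls among genes past the threshold whose arrays did not overlap between groups, passing over provisional symbols and antigen receptor segments, and for each list up to 4 members past the threshold with the largest change, or up to 2 members given as values where none passed.

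The analysis was tested on simulated data drawn from the real means and spreads, with 67, 67 and 66 of 18193 genes changed by 1, 2 and 3 log2 units. Recovered were 7.46%, 92.5% and 97.0% of them for carcinoma in situ against normal urothelium, 11.9%, 83.6% and 98.5% for invasive carcinoma against normal urothelium, and 31.3%, 91.0% and 98.5% for invasive carcinoma against carcinoma in situ. False calls made up 7.75%, 4.44% and 4.61% of the calls. Changes of 1 log2 unit were thus mostly missed in this simulation with 2 arrays per group. It changed far fewer genes than were called in the data (1597, 3652 and 999), which makes the adjusted threshold stricter. The recovery in the data may therefore be higher. Of 31 simulated lists the 1 shifted list was called and 0 others. To judge the overlap of both lesions, all 6 arrays were simulated 100 times with no difference between groups, both lesions sharing the simulated normal arrays. The spread of a gene was the same in all simulated groups.

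The alternatives fixed at that time were filters on dim genes, other ways to represent a gene, repeated quantile normalization, median centring, other variance models, array weights, fits of only the groups compared, the replicate number as a block, leaving out each array, other thresholds and other set tests. Those chosen after seeing the data left out normal array 2 and invasive array 1 together, averaged the carcinoma in situ arrays to 1 sample, or left out the genes of chromosomes X and Y or of chromosome 12. The replicate numbers in the titles did not come with any statement that they mark an animal, a litter or a day.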

Results

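Expression arrays were made from bladder urothelium of mice that were 8 months old. Cells were cut from frozen, stained bladder sections by laser capture, a method that lifts chosen cells out of a section under a microscope, so that each array reports on the tissue under the laser and not on the whole bladder. The 6 arrays fell into 3 groups of 2: normal urothelium of wild-type mice, carcinoma in situ, and invasive carcinoma. Both lesions came from mice that carried an H-ras transgene and lacked p53, and all animals were of the FVB/N strain. Carcinoma in situ is a flat, high-grade lesion confined to the epithelium, and the submitters named it as the step of tumour genesis and invasive carcinoma as the step of progression, with normal urothelium as the control. Genotype and lesion changed together against the normal group, and only the comparison between the lesions held the genotype constant. The labels did not tie the captured regions to animals, so p-values measured the spread between these arrays, which may be partly technical. The number of arrays, 2 per group, limited the precision.

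The array medians lay between 6.07 and 6.14 on the log2 scale. The paired arrays of a group were unequally close. The standard deviation of the log2 difference over genes was 0.22 between the carcinoma in situ arrays, 0.42 between the invasive arrays and 0.69 between the normal arrays, and 0.0440%, 3.21% and 13.7% of genes lay over 2-fold apart. The first principal component held 59.8% of the variance and ordered the groups from normal through carcinoma in situ to invasive carcinoma, and the second, with 23.6%, set carcinoma in situ apart from the others. Sex-linked transcripts also differed between arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty read 9.39, 8.28 and 7.88 in normal array 1 but 4.49, 2.90 and 4.16 in carcinoma in situ array 1 and 3.37, 2.84 and 5.02 in carcinoma in situ array 2. Xist, the transcript of the inactive X chromosome, read 6.85 in normal array 1 and 13.37 in normal array 2, although Kdm5d read 7.62 in the latter, and 10.28 in invasive array 1 beside a Kdm5d value of 6.58.

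**Figure D1:**
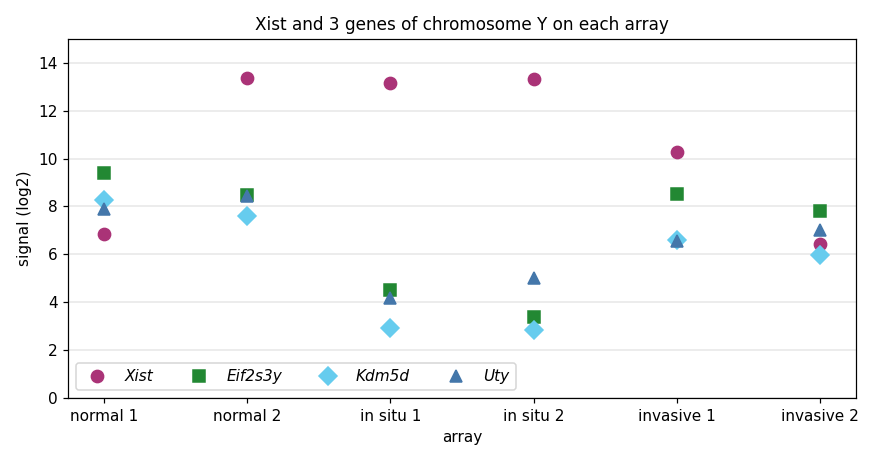
Log2 signal (vertical axis) of Xist and of 3 genes of chromosome Y on each of the 6 arrays (horizontal axis), 1 symbol per gene and array. Xist and the Y-linked genes were high together in normal array 2 and invasive array 1, and the Y-linked genes were lowest in both carcinoma in situ arrays, where Kdm5d read 2.90 and 2.84.

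The comparison of carcinoma in situ with normal urothelium asked what changed at tumour genesis. Most mitosis genes rose, as did the keratin genes Krt14 and Krt6a, and Krt20, Upk2 and Upk1a of the differentiated surface layer fell. Krt14, a keratin of basal cells, rose by 5.28 ± 0.49 on the log2 scale (38.8-fold, adjusted p = 0.00639), from 7.33 ± 1.11 to 12.60 ± 0.01 (mean ± SD, n = 2 arrays per group). Krt20, a keratin of the umbrella cells that line the bladder lumen, fell by 5.02 ± 0.53 (32.3-fold, adjusted p = 0.00810). Mki67, a marker of dividing cells, rose by 3.52 ± 0.18 (11.5-fold, adjusted p = 0.00330), and its 2 lesion arrays read 9.43 and 9.44 against 5.74 and 6.10 in the normal arrays. In limma's moderated test with Benjamini-Hochberg adjustment over 18193 genes, 1597 genes changed, 1044 up and 553 down. The count was not kept without either carcinoma in situ array: limma called 0 genes without array 1 of that group (2347 at an unadjusted p under 0.05), 0 without array 2 (2443) and 0 with both averaged to 1 sample (2318), an alternative chosen after seeing the data. The labels did not say whether these arrays hold separate animals or repeats of 1 sample. If the latter, the spread within this group is technical. As all groups share an estimate of the spread, technical spread would then enter the p-values of every comparison. This includes invasive carcinoma against normal urothelium, which compares no carcinoma in situ array. The count was 4196 without normal array 1, 3110 without normal array 2, 947 without either invasive array, and 6352 without both arrays that carried Xist and Y-linked signal together, also chosen after seeing the data.

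The 6 largest rises among genes with separate arrays were Clic6 (5.71 ± 0.47), a member of the chloride intracellular channel family, Ubd (5.59 ± 0.31), a ubiquitin-like modifier, the neutrophil chemokine gene Cxcl3 (5.53 ± 0.21), Il33 (5.49 ± 0.31), an alarmin of epithelial cells, Nptx1 (5.34 ± 0.43), a neuronal pentraxin, and Krt14 (5.28 ± 0.49), as log2 changes ± SE. The 6 largest falls were Ttr (-6.68 ± 0.23), which encodes a thyroid hormone carrier, Gpm6a (-5.65 ± 0.55), a membrane glycoprotein, Gt(ROSA)26Sor (-5.59 ± 0.47), a noncoding transcript, Meg3 (-5.56 ± 0.76), an imprinted noncoding RNA, the Y-linked Kdm5d (-5.08 ± 0.31) and Krt20 (-5.02 ± 0.53). Their adjusted p ranged from 0.00227 to 0.0151, and none of the 12 passed without either carcinoma in situ array, at 0 of 12 each. Of the 33 gene lists 21 passed camera, a set test that compares a list with all other genes at a preset correlation of 0.01 between genes. With a correlation estimated from the arrays 0 of the 33 lists passed, the lowest adjusted p being 0.152. Of 545 list genes 114 rose and 21 fell, and these calls were not kept without either carcinoma in situ array. Camera at the preset correlation draws its precision from the number of genes, so its calls hardly depend on leaving out an array.

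**Figure D2:**
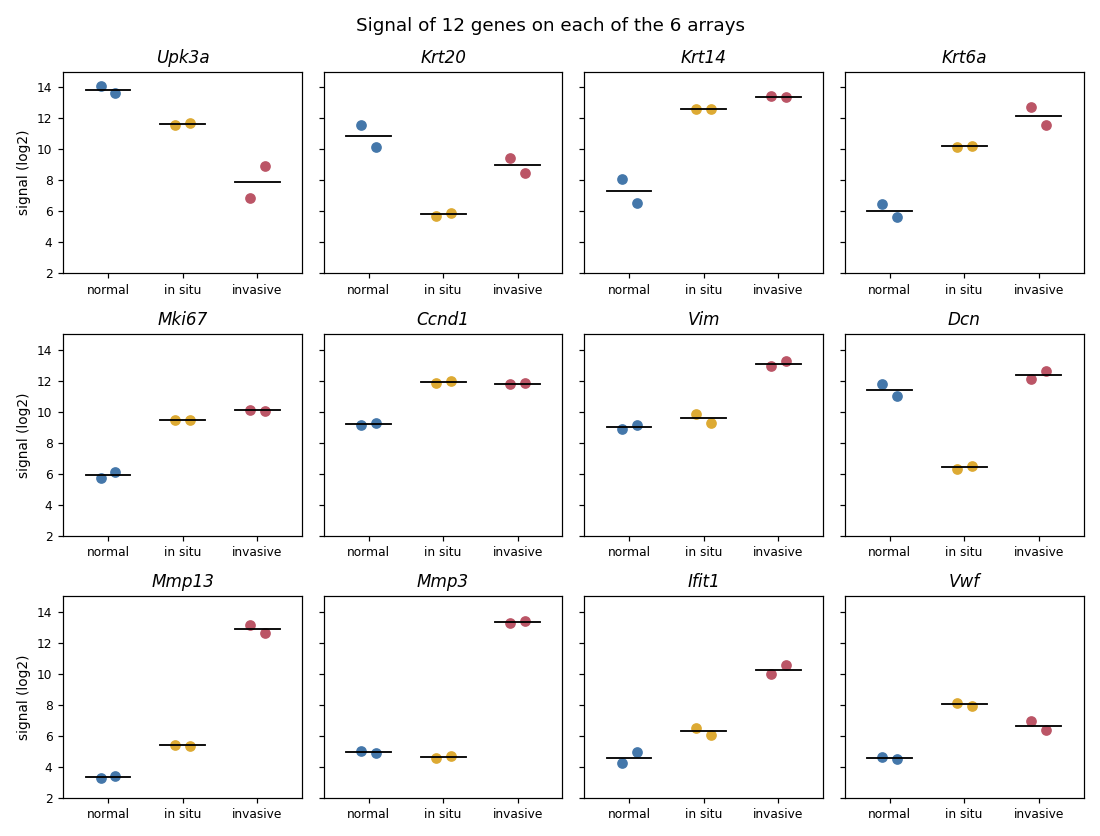
Log2 signal (vertical axes) of 12 genes in the 3 groups (horizontal axes), 1 point per array and a line at the mean of the 2 arrays of a group. Upk3a had a mean of 13.86 in normal urothelium, 11.65 in carcinoma in situ and 7.87 in invasive carcinoma, and only its difference between carcinoma in situ and normal urothelium did not pass (adjusted p = 0.104). Mki67 was high in both lesions, and Mmp3 was high only in invasive carcinoma, at a mean of 13.35.

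Of the luminal list, genes of urothelial differentiation, 0 of 20 rose, 3 fell and 17 did not pass (0 rose and 3 fell adjusted over the list alone). The list's median was -0.77 (camera adjusted p = 0.000989, adjusted p = 0.470 with an estimated correlation). The fallen genes were Krt20 (-5.02 ± 0.53, adjusted p = 0.00810) and the uroplakins Upk2 (-2.57 ± 0.30, adjusted p = 0.0107) and Upk1a (-2.08 ± 0.17, adjusted p = 0.00512), which build the plaques of the bladder surface. In the basal and keratinocyte list 4 of 18 rose, 0 fell and 14 did not pass (7 rose and 1 fell adjusted over the list alone). Its median was 0.98 (camera adjusted p = 0.000662, adjusted p = 0.460 with an estimated correlation). Krt14 (5.28 ± 0.49), Krt6a (4.15 ± 0.44), Col17a1 (2.62 ± 0.50), a collagen of hemidesmosomes, and Trp63 (1.76 ± 0.34), a transcription factor of basal epithelia, were among those that rose. Of the squamous and cornified envelope list 4 of 19 rose and 1 fell (4 rose and 1 fell adjusted over the list alone). The median of that list was -0.011, its mean 0.45 and the direction of its test up (camera adjusted p = 0.396). Sprr2f (3.27 ± 0.38), Tgm1 (2.42 ± 0.24), a transglutaminase, and Krt13 (1.96 ± 0.41) rose. Of the junction list 2 of 21 rose, 1 fell and 18 did not pass (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.319), the claudin genes Cldn3 (3.41 ± 0.29) and Cldn1 (2.75 ± 0.59) rising and Cldn8 (-2.99 ± 0.42) falling. Of the mesenchymal list 2 of 19 rose, 0 fell and 17 did not pass (2 rose and 0 fell adjusted over the list alone). These genes were S100a4 (1.78 ± 0.27) and Snai2 (1.62 ± 0.24) (camera adjusted p = 0.0237, adjusted p = 0.470 with an estimated correlation).

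The mitosis list had the lowest camera p of this comparison. There 18 of 23 rose, 0 fell and 5 did not pass (21 rose and 0 fell adjusted over the list alone), and the median was 2.18 (camera adjusted p = 1.16e-16, adjusted p = 0.152 with an estimated correlation). The examples were Birc5 (3.94 ± 0.29), Ube2c (3.57 ± 0.30), Mki67 (3.52 ± 0.18) and the checkpoint kinase gene Bub1 (3.49 ± 0.20). Among DNA replication genes 11 of 23 rose, 0 fell and 12 did not pass (16 rose and 0 fell adjusted over the list alone; camera adjusted p = 4.84e-08, adjusted p = 0.152 with an estimated correlation). Rrm2 (2.92 ± 0.16), a subunit of ribonucleotide reductase, and Mcm3 (2.07 ± 0.30), part of the replicative helicase, were among them. Of genes induced downstream of Ras and MAPK 10 of 21 rose, 0 fell and 11 did not pass (15 rose and 0 fell adjusted over the list alone). Their median was 1.43 (camera adjusted p = 2.35e-08, adjusted p = 0.152 with an estimated correlation). Dusp6 (4.12 ± 0.44), a phosphatase that acts on ERK, Ccnd1 (2.70 ± 0.15), cyclin D1, and Etv5 (2.33 ± 0.36) led the rises. Of the p53 target list 6 of 23 rose, 0 fell and 17 did not pass (6 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.0173, adjusted p = 0.262 with an estimated correlation). These included Phlda3 (2.07 ± 0.25), Gadd45a (1.75 ± 0.31) and the cell cycle inhibitor gene Cdkn1a (1.53 ± 0.19), all from mice described as lacking p53.

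In the stemness list 5 of 18 rose, 0 fell and 13 did not pass (8 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.000174, adjusted p = 0.152 with an estimated correlation). The transcription factor genes Sox2 (3.15 ± 0.26) and Sox9 (2.37 ± 0.22) and the retinaldehyde dehydrogenase gene Aldh1a3 (3.21 ± 0.64) were among them. Of the cytokine list 9 of 20 rose, 1 fell and 10 did not pass (10 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.000130, adjusted p = 0.152 with an estimated correlation). Cxcl5 (4.75 ± 0.27) rose beside Cxcl3 and Il33, and the acute phase gene Saa3 (-4.60 ± 0.71) fell. Of the interferon response list 8 of 19 rose, 0 fell and 11 did not pass (9 rose and 0 fell adjusted over the list alone; camera adjusted p = 1.15e-06, adjusted p = 0.152 with an estimated correlation). Xaf1 (3.87 ± 0.39), Mx1 (2.48 ± 0.29) and Ifit1 (1.69 ± 0.34) were among them. Beside these lists 1 of 17 macrophage markers rose, with a median of 0.86. For antigen presentation 2 of 14 rose, 0 fell and 12 did not pass (3 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.0377, adjusted p = 0.460 with an estimated correlation), the class II gene H2-Eb1 (2.60 ± 0.32) and the immunoproteasome gene Psmb8 (2.10 ± 0.18). Of the immediate early list 5 of 15 rose, 0 fell and 10 did not pass (5 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.000209, adjusted p = 0.152 with an estimated correlation). Jun (4.65 ± 0.27) and Egr1 (2.92 ± 0.26) led them. Of matrix proteases and the plasminogen system 3 of 18 rose, 1 fell and 14 did not pass (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.424). Adam8 (3.72 ± 0.56), Mmp7 (3.64 ± 0.34) and Mmp13 (2.02 ± 0.21) rose and Timp2 (-1.21 ± 0.17) fell.

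Cholesterol synthesis was the metabolic list with falls. There 0 of 16 rose, 7 fell and 9 did not pass (0 rose and 7 fell adjusted over the list alone; camera adjusted p = 9.67e-07, adjusted p = 0.262 with an estimated correlation), with a median of -1.26. The examples were Insig1 (-2.11 ± 0.19), a sterol sensor partner, and the enzyme genes Lss (-1.86 ± 0.38) and Hsd17b7 (-1.77 ± 0.16). In glycolysis and hypoxia 5 of 18 rose, 0 fell and 13 did not pass (14 rose and 0 fell adjusted over the list alone; camera adjusted p = 9.67e-07, adjusted p = 0.393 with an estimated correlation). The hexokinase gene Hk2 (2.22 ± 0.29) and Tpi1 (2.01 ± 0.27) were among them. In oxidative phosphorylation 2 of 22 rose, 0 fell and 20 did not pass (2 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.0491, adjusted p = 0.639 with an estimated correlation). Uqcrc1 (1.23 ± 0.26) and Sdhc (1.09 ± 0.16) rose. Among ribosomal proteins Rpl8 (0.86 ± 0.15) rose and 14 of 15 did not pass (1 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.00856, adjusted p = 0.460 with an estimated correlation). In xenobiotic and retinoid metabolism 0 of 22 rose, 0 fell and 22 did not pass (0 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.396). In the Notch list Notch4 (1.57 ± 0.25) rose and 16 of 17 did not pass (1 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.891), and in the Hedgehog and Wnt list Dkk3 (2.62 ± 0.23) rose, Wnt5a (-1.52 ± 0.28) fell and 15 of 17 did not pass (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.588).

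Markers of other cell types moved apart in this comparison. Of the endothelial list 10 of 15 rose, 0 fell and 5 did not pass (15 rose and 0 fell adjusted over the list alone; camera adjusted p = 1.10e-10, adjusted p = 0.152 with an estimated correlation). The von Willebrand factor gene Vwf (3.45 ± 0.24), Cdh5 (3.04 ± 0.43) and Emcn (2.88 ± 0.28) were among them. Of the fibroblast and collagen list 2 of 20 rose, 1 fell and 17 did not pass (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.161). Dcn, the decorin gene of fibroblasts, fell by 4.99 ± 0.32 from 11.39 ± 0.56 in normal urothelium, while Sparc (2.49 ± 0.42) and Pdgfrb (2.08 ± 0.44) rose. Of the smooth muscle list 1 of 14 rose, 1 fell and 12 did not pass (1 rose and 8 fell adjusted over the list alone; camera adjusted p = 0.000267, adjusted p = 0.460 with an estimated correlation), with a median of -1.01, Smtn (2.50 ± 0.20) up and Synm (-1.63 ± 0.16) down. Of the macrophage list 1 of 17 rose, 0 fell and 16 did not pass (5 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.00230, adjusted p = 0.460 with an estimated correlation). The rise was Ctss (1.88 ± 0.27). Of the B and plasma cell list 0 of 13 rose, 0 fell and 13 did not pass (0 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.0195, adjusted p = 0.552 with an estimated correlation). In the neutrophil list Clec4d (1.22 ± 0.26) rose (3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.161) and in the nerve and glia list Gfra3 (-1.14 ± 0.20) fell (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.352). For T and NK cells, erythroid cells and adipocytes 0 of 14, 0 of 6 and 0 of 7 members changed, and as many adjusted over the list alone (camera adjusted p 0.210, 0.159 and 0.368). In the sex list 0 of 4 rose, 3 fell and 1 did not pass (0 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.000989, adjusted p = 0.152 with an estimated correlation), the falls being Kdm5d, Eif2s3y (-5.01 ± 0.50) and Uty (-3.57 ± 0.36).

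The comparison of invasive carcinoma with normal urothelium set the lesion named as progression against the control. All mice were 8 months old, so no course over time was sampled. Most genes of the matrix protease, mesenchymal, fibroblast and collagen, and mitosis lists rose, and the uroplakin genes Upk3a, Upk2 and Upk1a fell. Mmp13, a collagenase, rose by 9.52 ± 0.21 on the log2 scale (733-fold, adjusted p = 0.000108), from 3.36 ± 0.11 to 12.88 ± 0.34 (mean ± SD, n = 2 arrays per group), and Mmp3, a stromelysin, by 8.41 ± 0.16 (339-fold, adjusted p = 0.000108). Vim, the intermediate filament of mesenchymal cells, rose by 4.08 ± 0.26 (16.9-fold, adjusted p = 0.000753), and Col1a1, a chain of the main fibrillar collagen, 32.1-fold (adjusted p = 0.000997). Upk3a, a uroplakin, fell by 5.99 ± 0.65 (63.4-fold, adjusted p = 0.00313). By limma 3652 of 18193 genes changed, 2295 up and 1357 down. The count was 1832 without either carcinoma in situ array, which enters only through the shared spread, 2177 without invasive array 1, 1637 without invasive array 2 and 5699 without normal array 2. Without both arrays that carried Xist and Y-linked signal together it was 8165, an alternative chosen after seeing the data.

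The 6 largest rises were Mmp13, Reg3b (8.61 ± 0.19), a secreted antimicrobial lectin, Mmp3, Cxcl3 (7.65 ± 0.21), Mmp7 (7.46 ± 0.34), matrilysin, and Cp (7.21 ± 0.21), ceruloplasmin. The 6 largest falls were Tmprss11a (-7.04 ± 0.25), a membrane serine protease, Ttr (-6.69 ± 0.23), Scube2 (-6.50 ± 0.34), Cyp4f15 (-6.42 ± 0.22), a cytochrome P450, Slc47a1 (-6.33 ± 0.39), an organic cation exporter, and Upk3a (-5.99 ± 0.65). All 12 passed without each of the 6 arrays in turn. Of the 33 lists 19 passed camera, and 0 passed with an estimated correlation, the lowest adjusted p being 0.0975. Of 545 list genes 218 rose and 38 fell.

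**Figure D3:**
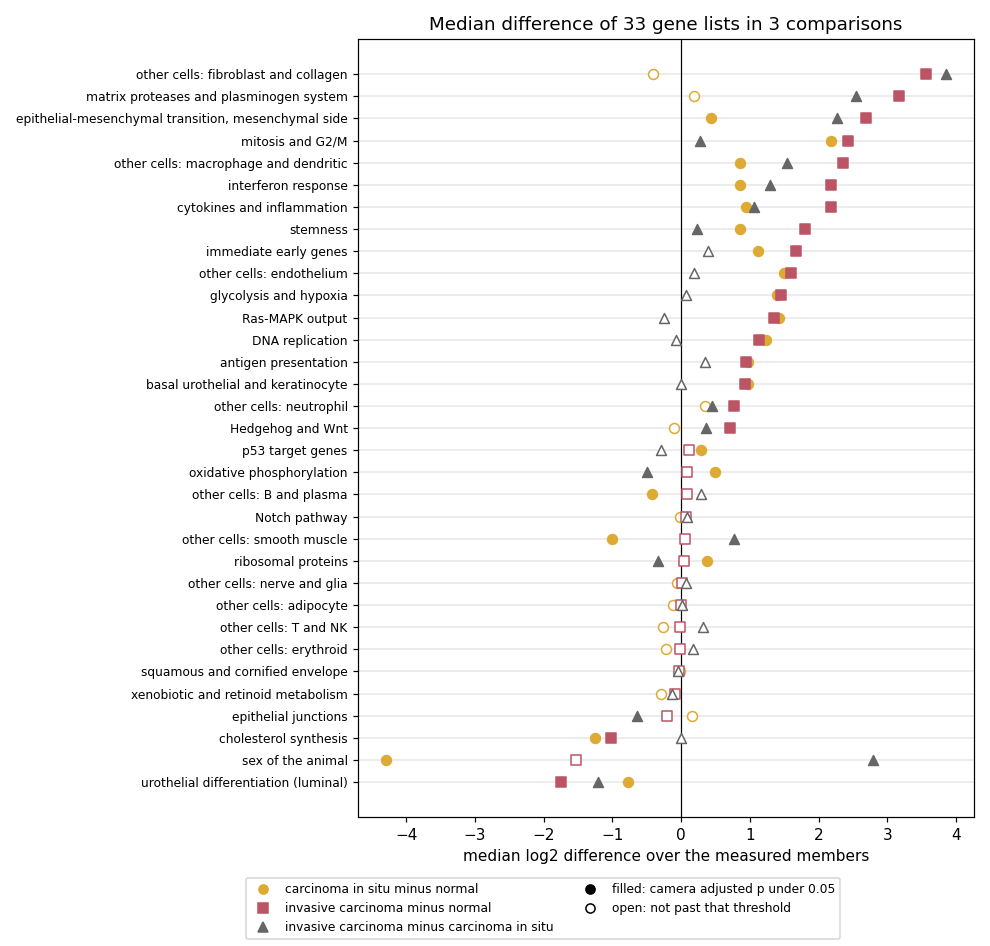
Median log2 difference over the measured members (horizontal axis) of each of the 33 gene lists (vertical axis), 1 symbol per comparison, filled where camera's adjusted p was under 0.05 at the preset correlation and open otherwise. The fibroblast and collagen list lay at -0.41 in carcinoma in situ against normal urothelium and at 3.56 in invasive carcinoma against normal urothelium, whereas the mitosis list lay at 2.18 and 2.43.

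Of the luminal list 0 of 20 rose, 11 fell and 9 did not pass (1 rose and 14 fell adjusted over the list alone), and its median was -1.74 (camera adjusted p = 4.56e-07, adjusted p = 0.274 with an estimated correlation). Beside Upk3a the falls included Snx31 (-4.10 ± 0.68), Upk2 (-4.05 ± 0.30) and Upk1a (-3.89 ± 0.17). Of the basal and keratinocyte list 8 of 18 rose, 0 fell and 10 did not pass (8 rose and 0 fell adjusted over the list alone; camera adjusted p = 2.61e-05, adjusted p = 0.295 with an estimated correlation). The keratins Krt6a (6.13 ± 0.44), Krt14 (6.07 ± 0.49), Krt17 (5.64 ± 0.26) and Krt6b (3.22 ± 0.34) were among them. In the squamous list 5 of 19 rose, 0 fell and 14 did not pass (5 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.887), among them Krt13 (8.01-fold, SE 0.41 in log2) and Krt4 (2.92 ± 0.42), and again the median, -0.037, lay below 0 while the mean, 0.39, and the test lay above it. Of the junction list 2 of 21 rose, 3 fell and 16 did not pass (2 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.318). Cldn8 (-5.68 ± 0.42) and Esrp2 (-1.79 ± 0.47), an epithelial splicing factor, fell and Cldn3 (4.12 ± 0.29) rose. Another junction gene, Pkp2, rose by 1.75 ± 0.23.

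In the mesenchymal list 15 of 19 rose, 0 fell and 4 did not pass (18 rose and 0 fell adjusted over the list alone), with a median of 2.70 (camera adjusted p = 5.65e-10, adjusted p = 0.173 with an estimated correlation). The examples were Vim (4.08 ± 0.26), the transcription factor genes Prrx1 (3.88 ± 0.22) and Zeb2 (3.87 ± 0.82), and the receptor tyrosine kinase gene Axl (3.49 ± 0.35). Of matrix proteases and the plasminogen system 16 of 18 rose, 0 fell and 2 did not pass (16 rose and 0 fell adjusted over the list alone; camera adjusted p = 9.22e-11, adjusted p = 0.0975 with an estimated correlation). The median was 3.17, and Mmp2 (5.25 ± 0.44) rose beside those above. Markers of fibroblasts and macrophages moved with these lists. Of the fibroblast and collagen list 12 of 20 rose, 0 fell and 8 did not pass (16 rose and 0 fell adjusted over the list alone), with a median of 3.56 (camera adjusted p = 3.92e-10, adjusted p = 0.274 with an estimated correlation) and Fbln2 (6.09 ± 0.35), Pdgfrb (5.77 ± 0.44) and Col5a2 (4.87 ± 0.28) among the rises. Of the macrophage list 14 of 17 rose, 0 fell and 3 did not pass (15 rose and 0 fell adjusted over the list alone; camera adjusted p = 3.49e-08, adjusted p = 0.245 with an estimated correlation). The complement genes C1qa (4.79 ± 0.55) and C1qb (4.28 ± 0.69) and the mannose receptor gene Mrc1 (4.02 ± 0.48) were among them. All members of the endothelial list rose, 15 of 15 (15 rose and 0 fell adjusted over the list alone; camera adjusted p = 2.11e-09, adjusted p = 0.0975 with an estimated correlation). Cdh5 (3.52 ± 0.43) and Cldn5 (2.42 ± 0.30) were among them.

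Most mitosis genes rose in invasive carcinoma too. Of the mitosis list 21 of 23 rose, 0 fell and 2 did not pass (21 rose and 0 fell adjusted over the list alone; camera adjusted p = 1.62e-13, adjusted p = 0.0975 with an estimated correlation). Birc5 (4.58 ± 0.29), Mki67 (4.16 ± 0.18) and Cdc20 (3.81 ± 0.21) led them. Of the replication list 11 of 23 rose, 1 fell and 11 did not pass (14 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.11e-05, adjusted p = 0.184 with an estimated correlation). Rrm2 (3.82 ± 0.16) and Mcm5 (1.73 ± 0.22) rose. Of the Ras and MAPK list 10 of 21 rose, 0 fell and 11 did not pass (12 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.000205, adjusted p = 0.245 with an estimated correlation). Dusp6 (3.52 ± 0.44), Ccnd1 (2.58 ± 0.15) and Fosl1 (2.27 ± 0.20) were among them. Of the p53 target list 6 of 23 rose, 2 fell and 15 did not pass (7 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.555). Plk2 (2.13 ± 0.29) and Phlda3 (1.78 ± 0.25) rose and Ei24 (-1.14 ± 0.25) fell. Of the stemness list 12 of 18 rose, 0 fell and 6 did not pass (14 rose and 0 fell adjusted over the list alone; camera adjusted p = 1.72e-06, adjusted p = 0.0975 with an estimated correlation). Prom1 (5.57 ± 0.28), which encodes CD133, Aldh1a3 (5.32 ± 0.64), the efflux transporter gene Abcg2 (4.44 ± 0.49) and Kit (8.03-fold, SE 0.42 in log2) were among them. Of the immediate early list 9 of 15 rose, 0 fell and 6 did not pass (10 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.61e-05, adjusted p = 0.0975 with an estimated correlation). Egr1 (4.12 ± 0.26) and Jun (3.77 ± 0.27) were among them. In the Notch list 2 of 17 rose, 2 fell and 13 did not pass (3 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.973), with Notch4 (2.23 ± 0.25) up and Notch1 (-1.57 ± 0.25) down, and in the Hedgehog and Wnt list 6 of 17 rose, 1 fell and 10 did not pass (8 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0210, adjusted p = 0.274 with an estimated correlation), with Wnt7a (2.91 ± 0.48) and Wnt10a (2.25 ± 0.20) up and Wnt5a (-2.37 ± 0.28) down.

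Most genes of the cytokine and interferon lists rose, beside 14 of 17 macrophage markers with a median of 2.36. Of the cytokine list 13 of 20 rose, 0 fell and 7 did not pass (16 rose and 0 fell adjusted over the list alone; camera adjusted p = 1.41e-09, adjusted p = 0.0975 with an estimated correlation). Ptgs2 (6.22 ± 0.49), the inducible cyclooxygenase, Cxcl5 (6.18 ± 0.27) and Lcn2 (5.32 ± 0.55) were among them. Of the interferon list 15 of 19 rose, 0 fell and 4 did not pass (16 rose and 0 fell adjusted over the list alone; camera adjusted p = 9.90e-11, adjusted p = 0.0975 with an estimated correlation). Ifit1 (5.68 ± 0.34), Xaf1 (5.63 ± 0.39) and Ifit3 (4.06 ± 0.17) were among them. For antigen presentation 3 of 14 rose, 0 fell and 11 did not pass (6 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.00515, adjusted p = 0.274 with an estimated correlation). The class II gene H2-Ab1 (3.12 ± 0.52) was among them. Of glycolysis and hypoxia genes 8 of 18 rose, 0 fell and 10 did not pass (12 rose and 0 fell adjusted over the list alone; camera adjusted p = 2.11e-05, adjusted p = 0.312 with an estimated correlation). Pgk1 (2.36 ± 0.28) and Hk2 (2.30 ± 0.29) were among them. In cholesterol synthesis 0 of 16 rose, 5 fell and 11 did not pass (0 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.000228, adjusted p = 0.274 with an estimated correlation). Lss (-2.19 ± 0.38) and Dhcr7 (-1.55 ± 0.15) were among them. In xenobiotic and retinoid metabolism 3 of 22 rose, 6 fell and 13 did not pass (4 rose and 7 fell adjusted over the list alone; camera adjusted p = 0.255), the falls led by the alcohol dehydrogenase gene Adh1 (-4.72 ± 0.54) and the glutathione transferase gene Gstm1 (-3.42 ± 0.24). In oxidative phosphorylation Sdhc (0.69 ± 0.16) rose (0 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.887) and among ribosomal proteins Rpl8 (0.83 ± 0.15) rose (1 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.887), with no other member past the threshold.

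Of the remaining cell type lists, smooth muscle had 3 rises and 2 falls of 14 (4 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.887). Acta2 (2.51 ± 0.38) rose and Mylk (-1.61 ± 0.29) fell. The neutrophil list had 4 rises of 12 (5 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0174, adjusted p = 0.274 with an estimated correlation). Clec4d (2.86 ± 0.26) and Trem1 (2.14 ± 0.25) were among them. In the T and NK list Cd3g (1.28 ± 0.24) rose (1 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.973), and in the B and plasma list Jchain (3.69 ± 0.77), the joining chain of secreted antibody, rose (1 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.906). In the erythroid list Bpgm (1.36 ± 0.35) rose and Alas2 (-1.01 ± 0.22) fell (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.768), and in the adipocyte list Fabp4 (-1.93 ± 0.41) fell (0 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.768). In the nerve and glia list Stmn2 (0.83 ± 0.17) rose and Uchl1 (-3.55 ± 0.58) and Gfra3 (-1.18 ± 0.20) fell (1 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.768). In the sex list Kdm5d (-1.68 ± 0.31) fell (0 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0523), and Xist, at 10.28 and 6.43 in the invasive arrays and 6.85 and 13.37 in the normal arrays, did not pass. The median, mean and test direction of the oxidative phosphorylation, Notch, T and NK, B and plasma, erythroid, adipocyte and nerve lists differed in sign.

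The comparison of invasive carcinoma with carcinoma in situ addressed progression within 1 genotype. Sex signal was not held constant, as Kdm5d read 2.90 and 2.84 in the carcinoma in situ arrays and 6.58 and 5.96 in the invasive arrays. Most genes of the matrix protease list and of the fibroblast and collagen list rose, with 9 of 19 of the mesenchymal list. Of 23 mitosis genes 0 passed the threshold, although 20 were higher in invasive carcinoma. Mmp3 rose by 8.74 ± 0.16 on the log2 scale (427-fold, adjusted p = 9.75e-05), from 4.62 ± 0.09 to 13.35 ± 0.08 (mean ± SD, n = 2 arrays per group), and Mmp13 by 7.50 ± 0.21 (181-fold, adjusted p = 0.000385). Dcn rose by 5.93 ± 0.32 (60.8-fold, adjusted p = 0.00138) and Vim by 3.51 ± 0.26 (adjusted p = 0.00265). Upk3a fell by 3.77 ± 0.65 (13.7-fold, adjusted p = 0.0320). By limma 999 of 18193 genes changed, 760 up and 239 down. The count was 89 without carcinoma in situ array 1, 50 without array 2 of that group, 428 without invasive array 2, 2493 without either normal array, and 54 with the carcinoma in situ arrays averaged to 1 sample. Without both arrays that carried Xist and Y-linked signal together it was 5897, of which 2757 were up, and like the averaging this was chosen after seeing the data.

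The 6 largest rises were Mmp3, Reg3b (7.74 ± 0.19), Mmp13, the homeobox gene Onecut2 (6.70 ± 0.36), Fbln2 (5.98 ± 0.35), a matrix fibulin, and Dcn (5.93 ± 0.32). The 6 largest falls were Fbp1 (-4.60 ± 0.21), a gluconeogenic phosphatase, Cxcl15 (-4.50 ± 0.33), Upk3a (-3.77 ± 0.65), Fam25c (-3.73 ± 0.47), Lipm (-3.44 ± 0.37) and Rptn (-3.21 ± 0.41), a cornified envelope protein. The 2 other probe sets of Rptn moved by -0.19 and 0.08 and were not called. Of the 12 genes named, 7 passed without each of the 6 arrays in turn. Of the 33 lists 16 passed camera, and 0 passed with an estimated correlation, the lowest adjusted p being 0.0859. Of 545 list genes 93 rose and 16 fell, against 18 and 0 without carcinoma in situ array 1 and 10 and 0 without array 2.

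Of matrix proteases and the plasminogen system 13 of 18 rose, 0 fell and 5 did not pass (15 rose and 0 fell adjusted over the list alone), with a median of 2.55 (camera adjusted p = 1.10e-16, adjusted p = 0.0859 with an estimated correlation). Timp1 (5.15 ± 0.34), a protease inhibitor, and Mmp2 (5.13 ± 0.44) were among them. In the mesenchymal list 9 of 19 rose, 0 fell and 10 did not pass (14 rose and 0 fell adjusted over the list alone), with a median of 2.27 (camera adjusted p = 6.10e-11, adjusted p = 0.280 with an estimated correlation). Its examples were Tnc (3.70 ± 0.52), a matrix glycoprotein, Prrx1 (3.51 ± 0.22), Vim (3.51 ± 0.26) and Twist1 (3.43 ± 0.25). The fibroblast and collagen list moved with them: 14 of 20 rose, 0 fell and 6 did not pass (18 rose and 0 fell adjusted over the list alone), with a median of 3.85 (camera adjusted p = 9.53e-20, adjusted p = 0.280 with an estimated correlation) and with Col1a1 (5.31 ± 0.36) and Col5a1 (5.16 ± 0.34) among the rises. Smooth muscle markers moved too, as 3 of 14 rose, 1 fell and 10 did not pass (5 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.000437, adjusted p = 0.453 with an estimated correlation). Tagln (4.67 ± 0.66) and Acta2 (3.84 ± 0.38) rose and Smtn (-1.03 ± 0.20) fell. Of the endothelial list Vwf (-1.39 ± 0.24) fell and 14 of 15 did not pass (0 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.175).

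Of the junction list 1 of 21 rose, 1 fell and 19 did not pass (1 rose and 2 fell adjusted over the list alone), namely Pkp2 (1.41 ± 0.23) and Cldn8 (-2.69 ± 0.42), with a list median of -0.64 (camera adjusted p = 0.00489, adjusted p = 0.556 with an estimated correlation). The rise of Pkp2 was not kept where probe sets open to cross-hybridization were left out, when its change was -0.039 (adjusted p = 0.980). Of the luminal list 1 of 20 rose, 4 fell and 15 did not pass (1 rose and 11 fell adjusted over the list alone; camera adjusted p = 8.84e-06, adjusted p = 0.398 with an estimated correlation). Upk3a (-3.77 ± 0.65), Upk1b (-2.41 ± 0.30) and Psca (-2.04 ± 0.39) fell and Krt20 (3.15 ± 0.53) rose. In the basal list 5 of 18 rose, 0 fell and 13 did not pass (7 rose and 2 fell adjusted over the list alone), including Krt17 (4.89 ± 0.26), Krt6b (2.79 ± 0.34) and Bnc1 (2.73 ± 0.29), while the median, -0.0083, lay below 0 and the mean, 0.58, and the test above it (camera adjusted p = 0.0717). In the squamous list Sbsn (1.24 ± 0.21) rose (1 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.690). Of the stemness list 3 of 18 rose, 0 fell and 15 did not pass (8 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.0103, adjusted p = 0.280 with an estimated correlation). These were Prom1 (4.64 ± 0.28), Abcg2 (3.96 ± 0.49) and Kit (2.77 ± 0.42).

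Of the cytokine list 10 of 20 rose, 0 fell and 10 did not pass (11 rose and 0 fell adjusted over the list alone; camera adjusted p = 4.13e-07, adjusted p = 0.246 with an estimated correlation). Lcn2 (4.96 ± 0.55), Saa3 (3.78 ± 0.71) and Il6 (2.95 ± 0.19) were among them. Of the interferon list 9 of 19 rose, 0 fell and 10 did not pass (13 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.06e-09, adjusted p = 0.246 with an estimated correlation). Ifit1 (3.99 ± 0.34), Ifit3 (3.20 ± 0.17) and Rsad2 (2.79 ± 0.36) were among them. Macrophage markers moved with both, as 6 of 17 rose, 0 fell and 11 did not pass (13 rose and 0 fell adjusted over the list alone; camera adjusted p = 4.28e-10, adjusted p = 0.280 with an estimated correlation). Mrc1 (3.16 ± 0.48) and C1qc (2.39 ± 0.39) were among them. In the neutrophil list Clec4d (1.64 ± 0.26) and Cd177 (1.31 ± 0.19) rose (3 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.00699, adjusted p = 0.358 with an estimated correlation). In antigen presentation H2-Eb1 (-2.19 ± 0.32) fell (0 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0922), and in the immediate early list Egr2 (2.84 ± 0.16) and Klf2 (2.56 ± 0.32) rose (5 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0624). In the B and plasma list Jchain (5.50 ± 0.77) rose (1 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.0568). In the T and NK list 0 of 14 and in the erythroid list 0 of 6 members passed, or 2 and 1 when adjusted over the list alone (camera adjusted p 0.143 and 0.479).

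Of the mitosis list 0 of 23 members passed, over all genes and when adjusted over the list alone, and the largest difference was that of Cdc20 (0.84 ± 0.21, adjusted p = 0.0956). The list's median was 0.28 (camera adjusted p = 0.00436, adjusted p = 0.376 with an estimated correlation). In DNA replication Rrm2 (0.90 ± 0.16) rose (1 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.814). In the Ras and MAPK list 0 of 21 members changed (0 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.0657). Etv5 (-1.65 ± 0.36, adjusted p = 0.0669) lay furthest from 0. In the p53 target list Fas (1.42 ± 0.25) rose and Ccng1 (-1.26 ± 0.21) fell (2 rose and 6 fell adjusted over the list alone; camera adjusted p = 0.0714). In the Hedgehog and Wnt list 4 of 17 rose, 0 fell and 13 did not pass (4 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.00387, adjusted p = 0.280 with an estimated correlation), with Wnt7a (2.62 ± 0.48) and Bmp4 (2.30 ± 0.25), and in the Notch list Rbpj (1.43 ± 0.16) rose and Notch1 (-1.30 ± 0.25) fell (1 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.811).

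In oxidative phosphorylation 0 of 22 and among ribosomal proteins 0 of 15 members changed, and as many when adjusted over each list alone. Camera nevertheless placed both below other genes, with medians of -0.50 (camera adjusted p = 0.00523, adjusted p = 0.589 with an estimated correlation) and -0.34 (camera adjusted p = 0.00924, adjusted p = 0.453 with an estimated correlation). In glycolysis and hypoxia 0 of 18 changed (0 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.793). In cholesterol synthesis Cyp51 (1.64 ± 0.26) and Insig1 (1.01 ± 0.19) rose (3 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.469), where the median, -0.0050, lay below 0 and the mean, 0.090, above it. In xenobiotic and retinoid metabolism 0 of 22 rose, 4 fell and 18 did not pass (2 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.378). Adh1 (-3.21 ± 0.54) and Gstm1 (-3.08 ± 0.24) were among them. In the adipocyte list Fabp4 (-2.11 ± 0.41) fell (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.814), and in the nerve and glia list Stmn2 (1.03 ± 0.17) rose and Snap25 (-2.24 ± 0.42) fell (1 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.873). In the sex list Eif2s3y (4.24 ± 0.50), Kdm5d (3.40 ± 0.31) and Uty (2.19 ± 0.36) rose (3 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.00594, adjusted p = 0.280 with an estimated correlation).

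Both lesions shared many of their differences from normal urothelium. Among the named genes Krt14, Krt6a, Mki67, Birc5, Ccnd1, Dusp6, Aldh1a3, Cxcl3 and Xaf1 rose, and Upk2, Upk1a, Ttr, Lss and Insig1 fell, in carcinoma in situ and in invasive carcinoma alike. In all, 843 genes rose and 451 fell in both comparisons, 1294 in the same direction, and 17 were called in opposite directions, 3 up in carcinoma in situ and down in invasive carcinoma and 14 the reverse. Independent lists of these sizes would share 131.7 rises and 41.2 falls. Unchanged groups that share simulated normal arrays had 0 calls in common in 100 simulations, but few genes can pass an adjusted threshold where no group differs, so this count says nothing about sharing. The log2 changes correlated over genes at r = 0.681, against 0.502 in the simulation, and their covariance was 0.523 against 0.0420 there, a difference of 0.481. The simulation gave all groups the same spread per gene, so its r of 0.502 follows from the shared group alone. The real normal arrays lay further apart (standard deviation of the log2 difference 0.69) than the carcinoma in situ (0.22) and invasive arrays (0.42). The simulated covariance is thus too low for these arrays, and the difference overstated. Genes are not independent replicates. The normal arrays were not split between the lesions, as this would leave 1 for each, so part of the excess may come from the shared arrays. Without either carcinoma in situ array the shared count was 0, as limma then called 0 genes in that lesion, without normal array 1 or 2 it was 3101 or 2569, and without invasive array 1 or 2 it was 648 or 677.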

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

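These tests were chosen after the report's results were seen. The comparisons above left out 10092 probe sets that had several gene names or none in the table used, control probe sets aside, and these are given as counts only. Fitted alone by limma, 166 of them were higher in carcinoma in situ than in normal urothelium and 763 lower, and 405 were higher in invasive carcinoma and 1553 lower. Between the lesions 113 were higher in invasive carcinoma and 37 lower. Those higher than in normal urothelium stand here because they lie outside the named genes, and no explanation was tested.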

How the results depend on the processing

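The runs without both arrays of mixed sex signal, with averaged carcinoma in situ arrays and without chromosomes X and Y or 12 were chosen after seeing the data. Counts follow the order carcinoma in situ against normal, invasive against normal, invasive against carcinoma in situ, shared by both lesions, and were 1597, 3652, 999 and 1294. Fewer genes tested (those below the median signal left out) gave 1064, 2222, 420 and 842. An unmoderated model gave 89, 998, 37 and 81, a fit of only the groups compared 947, 1832, 2493 and 658, and array weights 2709 for the lesions. An adjusted p under 0.10 gave 2638 for carcinoma in situ against normal, 1602 between the lesions and 2078 shared, and all probe sets 2653 and 6368 against normal and 2185 shared. Without both arrays of mixed sex signal the counts were 6352, 8165, 5897 and 4811, and with averaged carcinoma in situ arrays 0 (2318 at an unadjusted p under 0.05), 1828, 54 and 0. Leaving out 1 array at a time gave 0 to 4196, 1637 to 5699, 50 to 2493 and 0 to 3101 (a lone array was assumed to vary like the other groups), and 19 to 21, 19 to 21 and 16 to 20 lists. Camera at the preset correlation draws its precision from the number of genes, so list counts that stay alike without an array do not show that replicates agree. Of 21, 19 and 16 lists called by camera 0, 0 and 0 were called with an estimated correlation, and fry called 15, 20 and 9. The run with an estimated correlation also had far fewer degrees of freedom, so the lost calls do not measure correlation alone. Leaving out an array of the group not compared gave the same gene counts as the fit of only the groups compared. There only the pooled spread changed. Leaving out an array of a compared group both cuts it to 1 array and changes the pooled spread. For the other differences the cause was not tested. The replicate number as a replicate block gave 1146, 3315, 887 and 959 genes and 21, 20 and 18 lists. Deviations of same-numbered arrays from their group means correlated at -0.39, 0.37 and -0.34 between groups. The signs depend on the numbering, which was not taken to mark pairs. Normal array 1, carcinoma in situ array 2 and invasive array 1 thus deviated alike. Their upper quartiles were 8.07, 8.08 and 8.06. Those of normal array 2, carcinoma in situ array 1 and invasive array 2 were 7.98, 8.02 and 7.97. A source shared across groups was not tested, and the model takes the arrays as independent. Of 284 named gene results 194 had a value under all 21 settings, and of these 193 kept their direction and 41 also their call. The other 90, whose gene some settings left out, kept their direction wherever it was tested. Pkp2 reversed, to -0.039 (adjusted p = 0.980, not called) between the lesions without probe sets open to cross-hybridization, as another probe set then stood for it. Signal over background was not given, so no floor was set for dim genes.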

Other observations

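The tests in this part were chosen only after the results were seen, except that what copy loss and signal level predict for chromosome 12 was written down before their tests. Some genes moved 1 way at tumour genesis and back in invasive carcinoma. Dcn, the fibroblast proteoglycan gene, fell by 4.99 ± 0.32 in carcinoma in situ and rose by 5.93 ± 0.32 from there. Krt20 fell by 5.02 ± 0.53 and rose by 3.15 ± 0.53, and Saa3, an acute phase gene, fell by 4.60 ± 0.71 and rose by 3.78 ± 0.71. In cholesterol synthesis Insig1 fell by 2.11 ± 0.19 and rose by 1.01 ± 0.19, and Cyp51 fell by 1.55 ± 0.26 and rose by 1.64 ± 0.26. In the other direction Vwf rose by 3.45 ± 0.24 and fell by 1.39 ± 0.24, and the class II gene H2-Eb1 rose by 2.60 ± 0.32 and fell by 2.19 ± 0.32. The Y-linked genes did the same as Dcn: Kdm5d fell by 5.08 ± 0.31 and rose by 3.40 ± 0.31, Eif2s3y fell by 5.01 ± 0.50 and rose by 4.24 ± 0.50, and Uty fell by 3.57 ± 0.36 and rose by 2.19 ± 0.36. A difference of the carcinoma in situ samples other than the lesion, such as sex, thus gives this pattern as well. In all, 49 genes fell and then rose and 52 rose and then fell, against 23.1 and 13.7 for independent lists, while 111 rose and 43 fell at both steps, against 43.6 and 7.26. Both steps share the carcinoma in situ arrays, which alone gives opposite changes (simulated r over genes -0.499, observed -0.0424), so no excess is read from these counts. The simulated r follows from equal spread in all groups. The carcinoma in situ arrays lay closer together than those of the other groups, so it overstates this effect.

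Genes of chromosome 12 were lower in both lesions than in normal urothelium: over the brighter genes, 315 of them on this chromosome, the median log2 difference minus that of the other autosomes was -0.48 in carcinoma in situ and -0.49 in invasive carcinoma, and it was below in all lesion arrays against either normal array, from -0.37 to -0.59, with -0.05 between the normal arrays. Signal level does not account for this, since 0% of 10000 sets matched on signal level lay as low in either lesion, and neither do a few strongly changed neighbours, since all 10 of 10 blocks of neighbouring genes lay below the other autosomes in both. The fall was not even along the chromosome: block 9 lay at only -0.045 in invasive carcinoma, where the other blocks lay between -0.27 and -0.74. Matched sets also never lay as low as chromosome 13 in carcinoma in situ (-0.16) and chromosomes 1 (-0.18) and 9 (-0.28) in invasive carcinoma, nor as high as chromosome 17 in carcinoma in situ (0.20) and chromosome 8 in invasive carcinoma (0.16), so this test alone does not single out chromosome 12. A candidate explanation that stays open is loss of chromosome 12 copies in the lesion cells. Of 2973 runs of as many neighbouring genes on other autosomes 0% lay as low, the lowest being -0.17 in carcinoma in situ and -0.33 in invasive carcinoma. The runs overlap, and chromosome 12 had the lowest median of the autosomes in both comparisons, so this outcome was nearly settled beforehand. It does not weigh for copy loss. DNA was not measured here, and genotype changes with the lesion in this comparison, so the copy number itself is untested.

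Mesenchymal-side genes were higher in invasive carcinoma than in carcinoma in situ, by a median of 2.27. A lower share of epithelial cells that raised all other cell types alike would move their lists together. The endothelial list instead lay -3.66 from the fibroblast and collagen list (permutation of members, p = 0.00025, 100000 permutations). That p takes members as independent, while the estimated correlation within the fibroblast list was 0.68. A lower epithelial share made up mainly by fibroblasts is not set aside by this, and the luminal list had a median of -1.21. Fibroblasts in the captured regions may account for the pattern, since the fibroblast and collagen list, which shares 0 members with the mesenchymal list, rose by a median of 3.85 and Dcn, among its brightest genes, read 12.34 in invasive carcinoma, 6.41 in carcinoma in situ and 11.39 in normal urothelium, although laser capture was meant to leave stroma out. Mesenchymal expression by the carcinoma cells themselves cannot be told apart from this, because both would raise the same genes: the junction list had a median of -0.64, while Cdh1, the E-cadherin gene, chosen after its value was seen, differed by 0.033 ± 0.28.

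Y-linked genes were low in both carcinoma in situ arrays, and Xist and Y-linked genes were high together in normal array 2 and invasive array 1. Scaling between arrays, which would shift genes of similar signal alike, is argued against. The shift of Xist exceeded that of every Y-linked gene by at least 7.42 standard deviations of all genes' shifts in the pairs tested. These ran from each array low in Xist to the other array of its group and to the carcinoma in situ arrays. Pairs between normal and invasive arrays were not tested. An earlier test on percentile ranks did not reach its bound for Uty (gap of 18.7 points, standard deviation of 14.1). Tissue of both sexes within 1 sample may account for the double signal, but its test only restated the pattern. In normal array 2 the Y-linked genes lay at least 3.85 log2 units above the mean of the carcinoma in situ arrays and Xist 6.94 above the array lowest for it. A mixture should dilute each signal. Eif2s3y (8.49) and Kdm5d (7.62) lay below normal array 1 (9.39 and 8.28). Uty (8.44) lay above it (7.88), and Xist (13.37) lay no lower than in the carcinoma in situ arrays (13.17 and 13.33). The values thus leave this open. Of the genes called between carcinoma in situ and normal urothelium 3.51% lay on chromosomes X and Y, beside 3.45% of genes tested, but sex also changes autosomal genes and the carcinoma in situ arrays alone lack Y-linked signal, so sex and lesion cannot be told apart for these calls. The same holds for the calls between invasive carcinoma and carcinoma in situ. The sex of the animals was not in the labels.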
